A study of Homo sapiens with 4 samples.

How the data were processed

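Human primary CD8+ T cells, activated with antibody-coated beads, were profiled by droplet single-cell RNA sequencing in 4 libraries, 1 per group. The groups, per the labels, were cells before culture (day 0) and cells cultured for 3 days within a fast relaxing matrix of collagen without crosslinks, within a slow relaxing matrix of crosslinked collagen, or on a plate. Per the labels' protocols, the gels were digested with collagenase at 37 ºC, and the cells were strained and depleted of dead cells before loading on the 10x platform with version 3 chemistry.

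The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and cell barcode, without normalization, as the whole values in every file show. The authors made them with Cell Ranger on the GRCh38 build. Its version is given as 3.0.1 in the submitters' processing notes and as 3.1.0 per the file headers. Each matrix has 33538 rows and holds only barcodes that the authors' run had kept as cells. The smallest total of any barcode was 500 or 501 UMIs.

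The library before culture was used with the gene names of the other 3 libraries, whose features files were identical, since no features file of its own is listed. This row order was checked on the data. The Spearman correlation, over rows, of its summed counts with the fast, slow and plate libraries was 0.962, 0.962 and 0.959 in the given order, and at most 0.359 when the rows were shifted by 1. In 336 blocks of 100 rows the correlation with another library had a median of 0.96 and a lowest value of 0.328. Of its rows at 0, 88.8%, 87.9% and 89.4% were also at 0 in the fast, slow and plate libraries.

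Cells were kept with at least 1000 detected genes and at most 15% mitochondrial UMIs. Scrublet, run per library within scanpy 1.11.5, called 3, 5, 0 and 0 doublets in the libraries before culture, fast, slow and plate. The calls covered 0.046% of 6593 cells in the library before culture, below the minimum of 0.5% set for a working call in a library of over 5000 cells, so no doublets were removed. UMIs were summed over the kept cells of each library and scaled to CPM by the library's total. The totals were 210700062 UMIs before culture, 178385650 in the fast library, 154968018 in the slow library and 164234519 in the plate library. Each CPM has an exact Poisson 95% interval, which covers counting error only. Such intervals hold nothing of the variation between donors, cultures or library preparations.

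Fold differences are log2 ratios of CPM with a pseudocount of 1 CPM, over genes with at least 10 CPM in at least 1 of the libraries compared. With 1 library per group no test was run and no p-value is given. Genes at least 1.5-fold apart were counted as a description of 2 libraries. For 34 fixed gene lists, the median log2 fold of the members measured was placed among 10000 random lists of equal size matched on expression in 20 bins. A list is said to stand apart below percentile 2.5 or above percentile 97.5, as a description of these libraries, and needed at least 5 measured members. List members were counted as higher or lower at 1.25-fold or more. In every comparison many lists stood apart, some with small medians, such as G2M for slow over fast (−0.06, 0 of 51 members higher and 0 lower). So standing apart does not by itself mark a large or unusual difference. For 11 list symbols the older form used in the features files was looked up.

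The procedure was tested on Poisson counts simulated from the fast library's profile at the total UMIs of the slow and fast libraries, with 7148 genes tested. All 100 genes raised 2-fold and all 100 lowered 2-fold were recovered past 1.5-fold, and 0 unchanged genes were. Of 200 unchanged lists 9 fell outside the random range, and all 200 lists with 12 of 20 members raised were found. Such data hold counting error alone, without variation between cultures or preparations. The unchanged lists were genes drawn at random, so they do not cover lists whose members vary together.

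Named genes followed a rule fixed, with the lists, the comparisons and most alternatives, before the data were examined. For slow against fast it took the 10 highest and 10 lowest log2 folds, and for each matrix against the plate the 8 highest and 8 lowest by the smaller fold where both matrices went the same way. For day 3 against before culture it took the 8 highest and 8 lowest by the smallest of 3 folds. Such genes needed 20 CPM in a library compared and the same direction in the mean of cells' CPM. Mitochondrial, ribosomal protein, T cell receptor, immunoglobulin and clone-named genes and genes that vary between people were left out of the ranking. Each list that stood apart gave up to 4 members with the largest folds, and 4 lists (AP-1 family, cytotoxic, naive and memory, inhibitory receptor) gave any member. A few genes that the rule takes are not reported here. Coordinates come from GENCODE release 29 on GRCh38, joined by Ensembl identifier.

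Shares of cells with a UMI were computed after thinning each cell to 5000 UMIs, with exact Clopper-Pearson 95% intervals. Cells shallower than that (351 before culture, 45 fast, 95 slow, 18 plate) were left out of the shares. Cell cycle phase was called on thinned cells from fixed S and G2M lists. Cells of all libraries were clustered on 2000 variable genes without receptor segments, 30 components and 15 neighbours, with Leiden resolution 0.8. Clusters served to find cells other than T cells and to recompute values with some clusters left out, and a cluster counted as T cells where at least 90% of its cells had a CD3E UMI. Free RNA in the slow library was gauged from the level of CD3D, CD3E, CD3G, CD8A and CD8B in B cell-like cells.

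Every count, list median and named gene was recomputed under other cell filters, scalings (edgeR's TMM factors, DESeq2's median of ratios, a total without mitochondrial and ribosomal protein genes), gene filters and pseudocounts. Other settings used the mean over cells, thinned cells, cells with CD8A or CD8B and without CD4, and cells called G1. Of 17 settings, 3 were chosen after seeing the data, namely T cell clusters only, cells with the highest doublet scores left out, and cells above 2 times their library's median UMIs left out. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0. The raw reads were not used here.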

Results

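Single-cell RNA sequencing measured UMI counts in human primary CD8+ T cells in 4 libraries, with 1 library in each of 4 groups. The library before culture came from day 0, and the fast matrix, slow matrix and plate libraries came from day 3. In the deposited matrices they held 7990, 5545, 4132 and 4982 barcodes and 217996925, 183044477, 162556898 and 170107188 UMIs. The filter kept 6593, 4911, 3316 and 4334 cells, with median depths of 29809, 31935, 40879 and 33680 UMIs and medians of 5024, 5196, 5761 and 5311 detected genes. Median mitochondrial shares of the kept cells were 8.01%, 9.17%, 8.31% and 9.51%. With 1 library per group there were no replicates, so no difference below has a replicate check, and every interval covers counting error only.

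Most cells of each library were T cells. Clusters in which at least 90% of cells had a UMI of CD3E, a chain of the T cell receptor complex, held 86.0% of the cells before culture (95% interval 85.1 to 86.8), 98.7% in the fast library, 95.4% in the slow library and 99.4% in the plate library. Cells before culture lay mainly in T cell clusters numbered 1, 3 and 4 and cells at day 3 mainly in others, which the fast, slow and plate libraries shared in different proportions. CD8A, a chain of the CD8 coreceptor, had a UMI in 41.3%, 57.5%, 57.1% and 59.3% of cells thinned to 5000 UMIs, and in 76.2%, 88.2%, 87.1% and 89.8% of unthinned cells, in the order before culture, fast, slow and plate. In thinned cells of a B cell-like cluster, which should lack CD8A, 19 of 100 had a CD8A UMI before culture. CD4 had a UMI in 0.272%, 0.062%, 0.062% and 0.093% of thinned cells, against 1 of 100 B cell-like cells before culture.

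The comparison of the slow with the fast matrix addressed how T cells differ with the viscoelasticity of the matrix around them. Targets of the tumour suppressor p53 were higher in the slow library. The cell cycle inhibitor CDKN1A stood at 62.5 CPM in the slow library (95% interval 61.3 to 63.8) and 29 CPM in the fast library (28.2 to 29.8), a log2 fold of 1.08. MDM2, the ligase that degrades p53, stood at 134 against 62.5 CPM, a log2 fold of 1.09. Of the 18 measured members of the p53 and apoptosis list, 12 were higher and 1 lower in the slow library, and the median log2 fold was 0.74, at percentile 100 of the random lists. It was 0.47 and 0.39, still apart, with gene filters of 1 and 50 CPM. Without a cluster led by p53 targets, which held 659 slow and 119 fast cells, the list's median was 0.58. FDXR (1.00) and PHLDA3 (1.10) belonged to the list. TP53I3, a p53 target outside the list, stood at 21.4 CPM in the slow library (20.7 to 22.2) and 6.83 CPM in the fast library (6.45 to 7.22), a log2 fold of 1.52.

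The immediate early genes FOSB, FOS, ATF3 and JUN, which encode AP-1 transcription factors, were also higher in the slow library. FOSB stood at 48.0 CPM (46.9 to 49.1) against 14.3 CPM (13.7 to 14.8), a log2 fold of 1.68, and FOS at 40.0 CPM (39.0 to 41.0) against 14.0 CPM (13.4 to 14.6), a log2 fold of 1.45. ATF3 had a log2 fold of 1.31 and JUN of 1.06. The AP-1 family as a list did not stand apart, with 4 members higher, 0 lower and 10 between, a median log2 fold of 0.08 and percentile 94.4, though it did with a stricter cell filter (0.10) and with cells weighted equally (0.14). JUNB (0.03), JUND (0.08), BATF (0.19) and BATF3 (0.04) lay near 0.

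Other genes with the largest excess in the slow library were CYP1B1 (log2 fold 1.35), the myosin light chain MYL9 (36.5 against 14.7 CPM), the phosphatase DUSP1 (1.20), the connexin GJB2 (1.19) and IFNG (1.16). IFNG, the cytokine interferon gamma, stood at 87.2 CPM in the slow library (85.7 to 88.6) and 38.4 CPM in the fast library (37.5 to 39.4). In the heat shock and dissociation stress list, 6 of 22 measured members were higher and 1 lower, with a median log2 fold of 0.23 at percentile 100. HSPA1B (1.00) and IER3 (0.74) were higher, and IER2 (−0.65) was lower. In the NF-kB target list 4 of 19 members were higher and 1 lower, with a median of 0.18 at percentile 100, and TNFAIP3, an inhibitor of NF-kB signalling, had the largest log2 fold (1.01). In the T cell receptor response list 3 of 13 members were higher and 1 lower, with a median of 0.15 at percentile 99.8. TNFRSF4 (0.83) and the IL-2 receptor chain IL2RA (0.60) were higher, and EGR1 (−0.62) was lower. In the 248 fast and 228 slow cells called G1, the T cell receptor response median was −0.21, the NF-kB median −0.055, the cytokine and chemokine median −0.13 and the log2 fold of IFNG −0.27.

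CTLA4 (0.89) and ENTPD1 (0.54) were higher and CISH (−0.69) lower in the inhibitory receptor list, whose median of 0.22 over 8 members lay at percentile 100. The tissue residency list had a median of 0.11 over 9 members, at percentile 98.6. Of 5 measured markers of CD4 and regulatory T cells, 4 were higher in the slow library (CTLA4, TNFRSF4, CCR4 at 0.70 and IL2RA) with a median of 0.70 at percentile 100, while CD4 itself had a UMI in 0.062% of thinned cells of either matrix library. The cytokine and chemokine list, with 6 of 15 members higher and 2 lower, had a median of 0.18 at percentile 100 in the summed counts. Its median was −0.08 with cells thinned to equal depth and 0.04 with cells weighted equally. Within it CCL3 (1.04), CCL4 (0.99) and IL13 (0.98) were higher.

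The cholesterol synthesis list and some single genes of lipid synthesis were lower in the slow library. SCD, the stearoyl-CoA desaturase, stood at 16.2 CPM in the slow library (15.6 to 16.9) and 37.7 CPM in the fast library (36.8 to 38.6), a log2 fold of −1.17. SREBF1, a transcription factor of lipid synthesis, had a log2 fold of −1.13. In the cholesterol synthesis list 0 of 20 members were higher, 4 lower and 16 between (INSIG1 −0.41, DHCR7 −0.36, EBP −0.34, STARD4 −0.34), with a median of −0.24 at percentile 0. In the naive and memory list MAL (−1.03), LTB (−0.67) and KLF2 (−0.61) were lower, but the list did not stand apart (median −0.01, percentile 22.6). MAL was among the leading genes of T cell clusters 6 and 7. These held 585 and 513 cells of the fast library and 120 and 211 of the slow library. Its fold was not told apart from the mix of T cell clusters. The calcium-binding S100A4 stood at 770 CPM (765 to 774) against 1495 CPM (1489 to 1501).

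The interferon-induced exonuclease ISG20 had the lowest log2 fold (−1.31), and the type I interferon list had 0 of 19 members higher, 5 lower and a median of −0.07 at percentile 0.93. The cytotoxic effector list had 4 of 16 members higher, 2 lower and a median of −0.13 at percentile 0.01. The transcription factor ZEB2 (0.55) and the granule proteoglycan SRGN (0.55) were higher and the protease CTSW (−0.55) lower, and GZMB had a log2 fold of 0.35. The chemokine receptor list had 2 members higher, 2 lower and a median of −0.24 at percentile 0.18, and 0.01 with a stricter cell filter. Of 51 G2M members 0 were higher and 0 lower, with a median of −0.06 at percentile 0.06. AGTRAP (−1.02), SAMD3 (−0.95), the water channel AQP3 (−0.87) and the protease inhibitor TIMP1 (−0.85) were also among the lowest genes. Among lists that did not stand apart, median log2 folds were 0.01 for actomyosin and cytoskeleton, −0.06 for integrins, −0.03 for YAP/TEAD and mechanosensing, −0.05 for matrix proteolysis, −0.01 for glycolysis and −0.04 for hypoxia. They were −0.02 for S phase, 0.05 for MHC class II, −0.04 for quiescence, 0.10 for TGF-beta response and −0.06 for IL-2 and STAT5 targets. For oxidative phosphorylation, the amino acid and integrated stress response, and autophagy and lysosome they were 0.00, −0.03 and 0.00.

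In cells thinned to 5000 UMIs, CDKN1A had a UMI in 21.5% of cells in the slow library (20.1 to 23.0) and 13.1% in the fast library (12.1 to 14.0), and in 61.0% and 40.8% of unthinned cells. FOS had a UMI in 13.1% (11.9 to 14.3) and 4.64% (4.07 to 5.27) of thinned cells. No cell type here was known to lack CDKN1A or FOS, so the background of these shares was not measured. IFNG had a UMI in 19.1% (17.8 to 20.5) and 12% (11.1 to 13.0) of thinned cells, against 1 of 8 B cell-like cells in the slow library and 1 of 16 in the fast library. Of 7285 genes measured, 72 were at least 1.5-fold higher and 55 at least 1.5-fold lower in the slow library. Of the deposited barcodes, 5.06% in the slow library and 1.17% in the fast library had under 1% mitochondrial UMIs.

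Positions of the protein-coding genes that lead these comparisons were taken on GRCh38. CDKN1A (ENSG00000124762) lies on chromosome 6 from 36676460 to 36687339, and TP53I3 (ENSG00000115129) on chromosome 2 from 24077433 to 24085861. FOSB (ENSG00000125740) lies on chromosome 19 from 45467995 to 45475179, and FOS (ENSG00000170345) on chromosome 14 from 75278774 to 75282230. IFNG (ENSG00000111537) lies on chromosome 12 from 68154768 to 68159747, and SCD (ENSG00000099194) on chromosome 10 from 100347124 to 100364834. BNIP3 (ENSG00000176171) lies on chromosome 10 from 131966455 to 131982013, and KLF2 (ENSG00000127528) on chromosome 19 from 16324817 to 16327874.

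**Figure D1:**
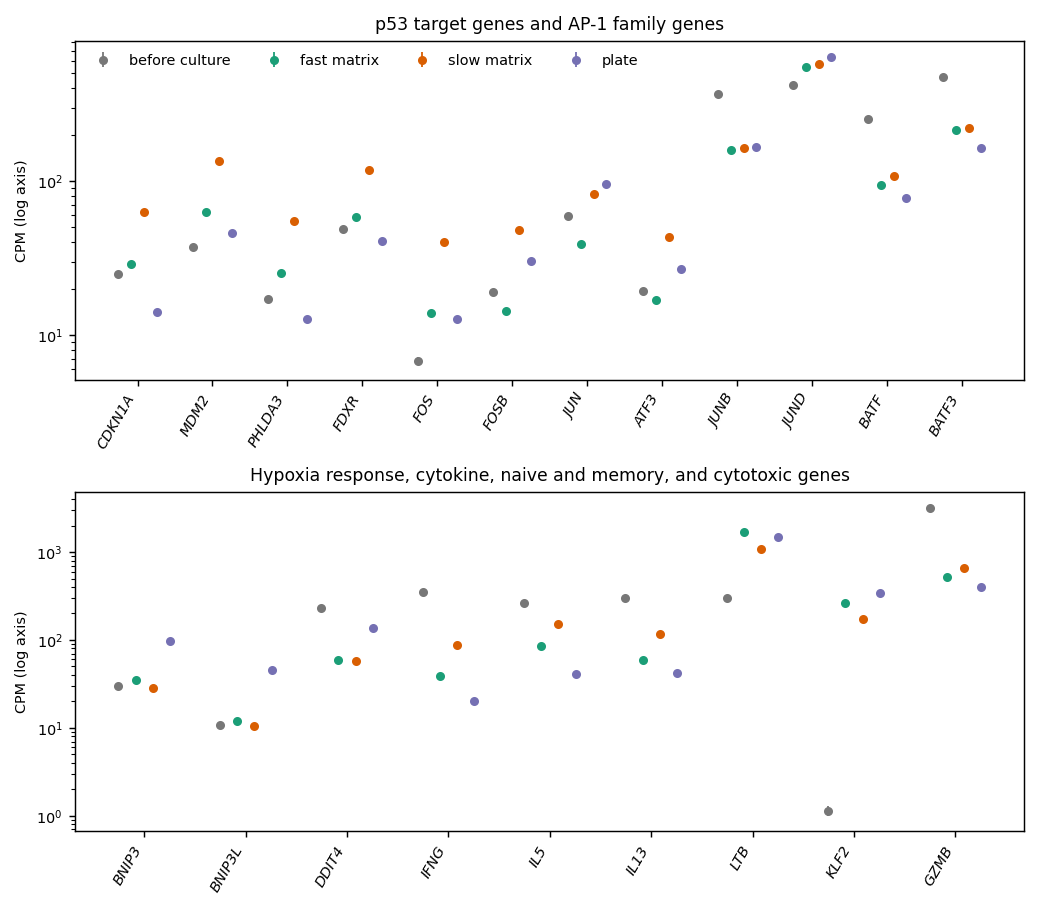
Level of 21 genes in the 4 libraries, in CPM on a log axis, with exact Poisson 95% intervals for counting error. CDKN1A stood at 62.5 CPM in the slow library and 29 CPM in the fast library, and BNIP3 at 97.8 CPM in the plate library and 34.9 CPM in the fast library.

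Each matrix was compared with plate culture of the same length, which addressed how culture within collagen differs from culture on plastic. Genes of the hypoxia response were lower in both matrix libraries than in the plate library. BNIP3, a mitophagy receptor induced in low oxygen, stood at 34.9 CPM in the fast library (34.0 to 35.8), 28.7 CPM in the slow library (27.9 to 29.5) and 97.8 CPM in the plate library (96.3 to 99.3), log2 folds of −1.46 and −1.74. Its relative BNIP3L had log2 folds of −1.82 in the fast and −2.01 in the slow library, and DDIT4, an inhibitor of mTOR signalling, of −1.19 and −1.22. In the hypoxia list 10 of 14 members were lower in the fast library (median −0.53) and 9 of 14 in the slow library (median −0.60), with 0 higher and percentile 0 in both. In the glycolysis list 7 of 19 members were lower in the fast library (median −0.25) and 8 in the slow library with 1 higher (median −0.30), both at percentile 0, with ALDOC at −1.66 and −2.52 and the lactate transporter SLC16A3 at −0.98 and −1.60.

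The p53 and apoptosis list was higher in both matrix libraries. In the fast library 6 of 16 members were higher and 1 lower (median 0.19, percentile 100, and 0.09 with a stricter cell filter), and in the slow library 12 of 18 were higher and 2 lower (median 0.78, percentile 100). CDKN1A had log2 folds of 0.98 and 2.07 over the plate library, where it stood at 14.2 CPM (13.6 to 14.8). PHLDA3 had log2 folds of 0.93 and 2.04, and GADD45A, which is induced by DNA damage, of 0.62 and 1.38. MDM2 (1.52) and FDXR (1.52) were higher in the slow library, and GADD45B (−0.65) was lower in the fast library.

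Cytokine genes were among those highest over the plate library. IL5 stood at 86.1 CPM in the fast library (84.7 to 87.5), 154 CPM in the slow library (152 to 156) and 41.5 CPM in the plate library (40.5 to 42.5), log2 folds of 1.03 and 1.86. IFNG had log2 folds of 0.90 and 2.06. In thinned cells IL5 had a UMI in 11.2%, 18.4% and 7.28% of cells of the fast, slow and plate libraries (25%, 36.6% and 17.5% unthinned), and in 0 of 16, 0 of 8 and 0 of 12 B cell-like cells (95% intervals up to 20.6%, 36.9% and 26.5%). The cytokine and chemokine list had 6 of 14 members higher and 3 lower in the fast library (median 0.12, percentile 99.3) and 7 of 15 higher and 2 lower in the slow library (median 0.26, percentile 100). LTA (−0.77) and CCL4 (−0.98) were lower in the fast library, and IL13 (1.46) and LIF (0.89) were higher in the slow library. The T cell receptor response list had medians of 0.16 (6 of 15 higher, 4 lower) and 0.44 (8 of 14 higher, 3 lower), at percentiles 100 and 100, and in the slow library −0.13 in cells called G1. NR4A1, an early gene of receptor signalling, was lower in both, at −1.69 and −1.87, while TNFRSF18 (0.78), CD69 (0.51) and EGR1 (0.92) were higher in the fast library and TNFRSF4 (0.88), TFRC (0.80) and IL2RA (0.76) in the slow library. These members had the largest folds in each library, and CD69 was higher than on the plate in the slow library as well. The connexins GJB2 (0.93 and 2.12) and GJB6 (0.83 and 1.59) and the myosin light chain MYL9 (0.87 and 2.13) were the other highest genes.

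Genes of cytotoxicity, of resting cells and of quiescence were lower in the matrix libraries as lists. The cytotoxic effector list had 3 of 17 members higher and 5 lower in the fast library (median −0.18) and 4 higher and 8 lower in the slow library (median −0.27), both at percentile 0, and the fast library's median was 0.20 in cells called G1. The granzymes GZMH (−1.16 and −1.69) and GZMK (−0.93 and −1.07) were lower, while GZMB (0.39 and 0.73) and the transcription factor PRDM1 (0.41 and 0.78) were higher. In the naive and memory list 3 of 16 members were lower in the fast library (median −0.15, percentile 0.01) and 6 in the slow library (median −0.24, percentile 0), with 0 higher in both. The transcriptional regulator ID3 had log2 folds of −1.51 and −1.37, and KLF2 of −0.37 and −0.98. In the quiescence list 4 of 12 members were lower in the fast library (median −0.25) and 7 in the slow library (median −0.35), both at percentile 0, with TSC22D3 at −1.71 and −0.65 and CDKN1B at −0.64 and −0.72. RGS1 (−1.51 and −1.20), METRNL (−1.41 and −1.10), TENT5C (−1.16 and −1.14) and the phosphodiesterase PDE4B (−1.09 and −1.24) were also lower in both.

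The MHC class II list had medians of −0.24 and −0.23 (2 of 10 members lower in each, percentiles 0 and 0.04), the G2M list of −0.08 and −0.13 (percentiles 0 and 0) and the cholesterol synthesis list of −0.09 (1 of 20 lower, percentile 0.13) and −0.31 (10 of 20 lower, percentile 0). IL-2 and STAT5 targets had medians of −0.09 (percentile 0.82) and −0.15 (percentile 0.31), with SOCS1 at −0.75 and −0.82 and DUSP5 at −0.81 and −0.70. In the fast library alone, the NF-kB (−0.12, percentile 0.05), heat shock and dissociation stress (−0.14, percentile 0), TGF-beta (−0.21, percentile 0.07) and inhibitory receptor (−0.10, percentile 1.69) lists stood apart below, and the YAP/TEAD and mechanosensing list above (0.15, percentile 98.7, 0 of 6 members higher or lower). The difference between the matrices in these lists was not tested. The markers of CD4 and regulatory T cells had a median of 0.47 over 5 members in the slow library (percentile 100), and too few were measured in the fast library.

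The AP-1 family did not stand apart in the fast library (median −0.05, percentile 5.34) or in the slow library (median 0.10, percentile 86.1). JUN (−1.26), FOSB (−1.03), FOSL2 (−1.01) and ATF3 (−0.65) were lower in the fast library than in the plate library. FOS (1.59), ATF3 (0.66) and FOSB (0.65) were higher in the slow library, where FOSL2 (−1.20) was lower and JUN had a log2 fold of −0.20. Of 7271 genes measured, 15 were at least 1.5-fold higher and 69 lower in the fast library, and of 7371, 124 were higher and 158 lower in the slow library. Both comparisons used the same plate library, so its own level enters both sets of values. With a gene filter of 50 CPM the fast library's medians were −0.09 for cytokines, 0.04 for IL-2 and STAT5 targets and 0.13 for the p53 list, which then no longer stood apart. The cytokine median there was −0.004 without cells above 2 times the median UMIs, and the T cell receptor response list had medians of −0.11 and −0.06 in the fast and slow libraries with a gene filter of 1 CPM.

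**Figure D2:**
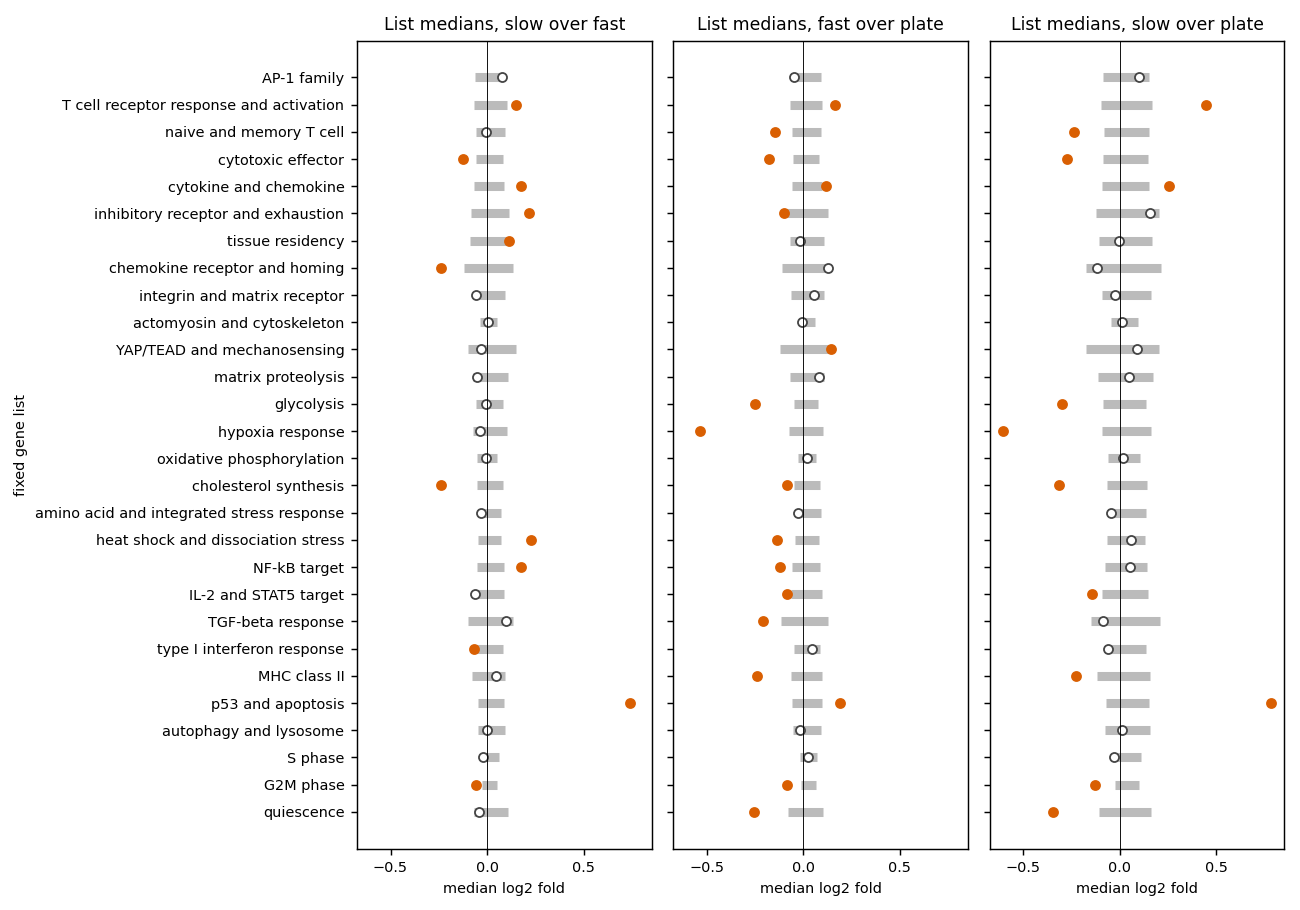
Median log2 fold of the fixed gene lists for slow over fast, fast over plate and slow over plate, with grey bars for the range that holds 95% of random list medians and filled orange points for lists outside it. The p53 and apoptosis list lies at 0.74, 0.19 and 0.78, and the hypoxia response list at −0.04, −0.53 and −0.60.

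Each day 3 library was compared with the cells before culture, which addressed how the starting population differs from the cultured cells. Cytokine genes were much lower at day 3 in each culture. IL9 stood at 462 CPM before culture (459 to 465) and 1.46 CPM in the fast library (1.29 to 1.65), 4.27 CPM in the slow library (3.95 to 4.61) and 0.298 CPM in the plate library (0.221 to 0.394). In the cytokine and chemokine list 16 of 21 members were lower and 3 higher in each culture, with medians of −2.70, −1.96 and −2.51 in the fast, slow and plate libraries, all at percentile 0. LTA had log2 folds of −5.29, −5.06 and −4.52, IL3 of −4.50, −4.98 and −4.88, the chemokine CCL17 of −5.51, −6.73 and −5.02, and the chemokine CXCL10 of −4.49, −4.51 and −4.50. CCL1 stood at 51.0 CPM before culture and at 0.017, 0.019 and 0.055 CPM at day 3. IFNG had log2 folds of −3.16, −2.00 and −4.06.

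KLF2, a transcription factor of T cell quiescence and trafficking, had the largest excess at day 3 among the genes ranked. It stood at 1.15 CPM before culture (1.01 to 1.30) and at 265 CPM (262 to 267), 174 CPM (171 to 176) and 342 CPM (339 to 345) in the fast, slow and plate libraries, log2 folds of 6.95, 6.34 and 7.32. In thinned cells KLF2 had a UMI in 0.561% of cells before culture, with 0 of 100 B cell-like cells (95% interval up to 3.62%), and in 60.9%, 44.6% and 67.4% at day 3, with 3 of 16, 3 of 8 and 1 of 12 B cell-like cells. Unthinned, the KLF2 shares were 1.79%, 85.1%, 72.7% and 89.4%. In the quiescence list 10 of 12, 10 of 11 and 11 of 12 members were higher and 0 lower, with medians of 0.95, 0.86 and 1.16 at percentile 100. SLFN5 (1.95, 1.68 and 1.91) was among them, and TSC22D3, a glucocorticoid-induced gene, was higher in each (1.12, 2.18 and 2.83). In the naive and memory list, LTB (2.51, 1.84 and 2.31) and S1PR1, the receptor for egress from lymphoid tissue (1.67, 1.75 and 1.92), were higher, while CCR7 (−2.37, −2.21 and −1.98), TCF7 (−1.47, −1.42 and −1.49) and CD27 (−1.77, −2.02 and −1.45) were lower. The list's medians were −0.10, −0.16 and 0.45, and it stood apart in the plate library alone (percentile 99.9).

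The T cell receptor response and NF-kB lists were lower at day 3 in their medians, with members on both sides. The T cell receptor response list had 10 of 17, 10 of 16 and 12 of 17 members lower and 5, 4 and 4 higher, with medians of −0.88, −0.67 and −0.57 at percentiles 0, 0 and 0.09. TNFRSF4 (−2.82, −1.99 and −2.87) and CRTAM (−3.30, −3.38 and −2.93) were lower in each, and CD69 (1.71, 1.86 and 1.20) was higher. The NF-kB list had 16, 16 and 15 of 21 members lower, 2, 2 and 1 higher and medians of −0.94, −0.81 and −0.81 at percentile 0, with TRAF1 at −2.34, −1.89 and −2.32 and NFKB2 at −1.96, −1.70 and −1.71. The heat shock and dissociation stress list had medians of −0.44, −0.27 and −0.29 (percentiles 0.01, 0.3 and 2.02), but within T cell clusters it no longer stood apart in the slow (−0.20, percentile 2.89) and plate (−0.21, percentile 7.6) libraries. In it IER3 (−3.37, −2.63 and −2.62) was lower and ZFP36, which destabilises cytokine mRNA, was higher (2.64, 2.59 and 3.42). In the AP-1 family, BATF (−1.43, −1.24 and −1.69), BATF3 (−1.14, −1.10 and −1.52) and JUNB (−1.20, −1.17 and −1.13) were lower and MAF (1.04, 0.90 and 1.40) was higher. The list stood apart in the fast library alone (median −0.28, percentile 1.94), with medians of 0.17 and 0.18 in the slow and plate libraries, and no longer did within T cell clusters (−0.26, percentile 3.96).

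The granzymes went in opposite directions. GZMB stood at 3209 CPM before culture and 520, 662 and 398 CPM at day 3, log2 folds of −2.62, −2.27 and −3.01, while GZMA (1.75, 1.85 and 1.67) and GZMK (1.60, 1.46 and 2.53) were higher. The cytotoxic effector list as a whole had medians of 0.22, 0.32 and 0.55 at percentiles 98.6, 99.7 and 100. The slow library's median was −0.062 with cells weighted equally, and the fast library's 0.37 within T cell clusters. In the inhibitory receptor list LAG3 (−1.55, −1.26 and −1.44) and CTLA4 (−1.58, −0.69 and −1.02) were lower and CD96 (1.21, 1.44 and 1.31) was higher. Its medians were −0.33, −0.56 and −0.31, apart in the slow library alone (percentile 0.04). The markers of CD4 and regulatory T cells had medians of −1.58, −0.69 and −1.28 at percentiles 0.01, 0.12 and 0.02, with TNFRSF4, CTLA4 and CCR4 (−1.62, −0.93 and −1.40) lower.

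Genes of adhesion and the cytoskeleton were higher at day 3, in the plate library as well as in the matrix libraries. The integrin and matrix receptor list had 10, 9 and 9 of 14 members higher and 1 lower in each, with medians of 0.54, 0.40 and 0.52 at percentiles 100, 99.9 and 99.9. The collagen receptor LAIR1 (3.28, 2.91 and 3.12) and the integrin chains ITGA4 (2.28, 2.32 and 2.18) and ITGA2 (2.18, 2.35 and 2.17) were higher and ICAM1 (−1.82, −1.80 and −1.90) was lower. The actomyosin list had medians of 0.44, 0.46 and 0.51 at percentile 100, with VIM at 1.09, 1.12 and 1.09 and the lamin LMNA lower at −1.66, −1.11 and −1.33. The matrix proteolysis list had medians of 0.68, 0.52 and 0.66 (percentiles 100, 99.9 and 100), the slow one −0.061 with a gene filter of 50 CPM, with the metalloproteinase MMP25 at 3.08, 2.69 and 2.92 and LGALS3 at 1.83, 1.59 and 2.04. Others among the highest genes were RASGRP2 (4.44, 4.08 and 4.12), ANTXR2 (2.97, 2.97 and 2.84) and RAB37 (2.84, 2.54 and 3.11).

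The G2M list had medians of 0.54, 0.49 and 0.65 at percentile 100, with KIF11 at 1.04, 0.97 and 1.01, and the S phase list had medians of 0.04, −0.06 and 0.02 and did not stand apart. The MHC class II list had medians of 0.64, 0.57 and 0.93 (percentiles 100, 100 and 100). The p53 and apoptosis list had medians of 0.31 (percentile 99.0) in the fast library, 1.00 (percentile 100) in the slow library and −0.02 (percentile 55.6) in the plate library, and MDM2 had log2 folds of 0.72 in the fast and 1.81 in the slow library. The hypoxia list stood apart in the plate library alone (median 0.60, percentile 99.9), with BNIP3L at 1.96, NDRG1 at 1.88 and BNIP3 at 1.69, and had medians of 0.10 and −0.05 in the fast and slow libraries. The cholesterol synthesis list had medians of 0.22, 0.10 and 0.30 and stood apart in the fast (percentile 97.8) and plate (percentile 99.3) libraries, the fast one no longer within T cell clusters (0.20, percentile 96.6), with INSIG1 at 1.93 and 2.13. The chemokine receptor list stood apart in the slow (0.64) and plate (0.63) libraries, the tissue residency list in the plate library (0.67) and the YAP/TEAD and mechanosensing list in the slow library (0.57, percentile 98.3).

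Genes at least 1.5-fold higher and lower than before culture numbered 877 and 830 of 7549 in the fast library, 855 and 691 of 7544 in the slow library, and 1014 and 1025 of 7589 in the plate library. HBD (365 CPM before culture; 2.23, 1.39 and 0.024 CPM at day 3) and HBG2 (55.8 CPM before culture; 0.247, 0.006 and 0.012 CPM at day 3), chains of haemoglobin, were among the lowest, and 362 of the 6593 cells before culture lay in a cluster led by haemoglobin genes. The type I interferon list had medians of −0.26, −0.52 and −0.35 at percentiles 1.2, 0 and 0.34, with IFI27 at −2.79, −2.50 and −2.85, but lay at percentiles 32.9, 17.9 and 72.7 when T cell clusters alone were compared, and the plate median was 0.16 with a gene filter of 50 CPM. In the 150 to 248 cells called G1 per library, which were not limited to T cell clusters, the MHC class II medians were −0.62, −0.45 and −0.22 and the G2M medians −0.12, −0.13 and −0.08. Matrix proteolysis was there −0.035 (slow) and −0.067 (plate), and in the slow library cytotoxic genes were −0.12, inhibitory receptors 0.028 and CD4 and regulatory T cell markers 0.21.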

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

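Of the tests in this part, those of digestion of the gels alone, of a stronger digestion response, of the cluster led by p53 targets and of damaged cells low in mitochondrial UMIs were chosen after the result was seen. With 1 library per group the differences between the matrices given here were not tested.

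FOSB and ATF3 lay below the plate library in the fast matrix and above it in the slow matrix. FOSB had a log2 fold of −1.03 over the plate library in the fast matrix and 0.65 in the slow matrix, and 1.68 for slow over fast. For ATF3 these values were −0.65, 0.66 and 1.31. The chemokine CCL3 went the same way, with −0.49, 0.55 and 1.04, as did the inhibitory receptor CTLA4, with −0.56, 0.33 and 0.89. Barcodes outside the cell filter made up 19.7% of the slow library and 13.0% of the plate library.

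The immediate early genes FOS, FOSB, JUN and ATF3 were higher in the slow than in the fast library, with a median log2 fold of 1.38, and handling of the cells may account for such genes. Digestion of both gels alone would place both matrix libraries above the undigested plate library. The median over plate in the fast library was −0.84, though FOS was not lower there. These genes were the AP-1 members higher in slow than in fast, and a lower level in the fast matrix could hide a digestion response. So the value cannot exclude digestion as a part of the difference. A greater weight of deeper cells in the summed counts is argued against by 1.44 with cells thinned to equal depth, which does not test whether deeper cells differ. Damaged cells low in mitochondrial UMIs are argued against by 1.34 with these left out under the stricter cell filter. Among cells with equal p53 list UMIs the median was 1.19, against 1.44 over all thinned cells. The cluster led by p53 targets, which held 659 slow and 119 fast cells, had FOS among its leading genes. With its cells left out the median was 1.15, against 1.38, so that it carried part of the difference. Were this cluster the only source, free RNA would have to carry 75.6% of the excess. Free RNA was not measured closely, so 1.15 argues against this cluster as the whole cause only if free RNA did not carry the rest. The value at equal p53 list UMIs cannot decide on cells rich in them. Thinned cells had medians of 6 (slow) and 5 (fast) such UMIs, so cells with equal counts may still differ in p53 list level. A stronger digestion response in the slow library cannot be told apart from the matrix, since 4 of 11 other immediate early members of the dissociation list were higher there, between the counts that either reading requires. The viscoelasticity of the matrix stays open and untested, since matrix, library and digestion of each gel coincide.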

How the results depend on the processing

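The settings with T cell clusters only, with the highest doublet scores left out and without cells above 2 times the median UMIs were chosen after seeing the data. Of list medians across settings, 297 of those that lead a comparison and 2204 of the others stayed on their side of the random range, and those within it had either sign. Another 2 and 120 left the range, 3 and 85 entered it, and 2 and 25 reversed. Of named gene values 8117 stayed within their counting interval, 3127 moved beyond it and 52 reversed, and of shares of cells 1556 stayed and 1048 moved. The gene filters of 1 and 50 CPM cannot move a named gene's fold, so the 706 values that stayed under each were fixed in advance. Of the shares that moved, 850 did so with unthinned cells, where more UMIs per cell raise shares. The p53 list ranged from 0.39 to 0.84 for slow over fast, and the hypoxia list from −0.78 to −0.43 for fast over plate and from −0.81 to −0.50 for slow over plate, and both stood apart in every setting. No list or named gene reversed under the 3 scaling alternatives, which shift all folds of a comparison by nearly the same amount. Keeping called doublets gives the values reported, since none were removed. No paired analysis was possible because each group has 1 library, and no library could be left out. Depth limits genes near 1 CPM and the B cell-like shares at day 3, which rest on 8 to 16 cells.

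With a gene filter of 1 CPM, which tests more genes, genes at least 1.5-fold higher numbered 148 (slow over fast), 33 (fast over plate), 230 (slow over plate), and 1419, 1340 and 1649 for fast, slow and plate over before culture. Genes lower numbered 102, 129, 314, 1440, 1231 and 1610 in the same order. With 50 CPM, which tests fewer, the higher genes numbered 25, 2, 48, 321, 300 and 372 and the lower 18, 24, 45, 330, 273 and 445. A pseudocount of 5 CPM, which shrinks folds of low genes, gave 82 higher and 103 lower for slow over plate and 32 lower for slow over fast. In cells called G1, of which there were 150, 248, 228 and 233 before culture and in the fast, slow and plate libraries, higher genes numbered 382, 162 and 570 for slow over fast, fast over plate and slow over plate. Lower genes there numbered 289, 191, 342, 1884, 1461 and 1975 in the order above. Fewer cells widen the counting error of such counts. The cells called G1 held 2036158, 4293967, 4670117 and 4631986 UMIs in all, in the same library order, and were not limited to T cell clusters.

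For slow over fast, the AP-1 family stood apart with the stricter cell filter (0.10) and the mean of cells (0.14). The cytokine list no longer stood apart with the stricter filter (0.082) and the mean of cells (0.036), and reversed with thinned cells (−0.08) and in G1 cells (−0.13). The chemokine receptor list reversed with the stricter filter (0.008). The p53 list of fast over plate no longer stood apart at 50 CPM (0.13). The cause was not tested for these, nor for the reversals that follow. With 1 CPM the T cell receptor response list reversed for fast (−0.11) and slow (−0.058) over plate. With 50 CPM IL-2 and STAT5 targets (0.036) and cytokines (−0.088) reversed for fast over plate, matrix proteolysis for slow over before culture (−0.061) and type I interferon for plate over before culture (0.16). The last also reversed in T cell clusters (0.048). The cytokine list of fast over plate reversed without cells above 2 times the median UMIs (−0.004), and the cytotoxic list of slow over before culture with the mean of cells (−0.062). GNLY reversed for slow over before culture with thinned cells (−0.017) and the mean of cells (−1.11), and for plate over before culture with the mean of cells (−0.70).

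In G1 cells, the G2M medians over before culture were −0.12, −0.13 and −0.079 for fast, slow and plate, and those of MHC class II −0.62, −0.45 and −0.22. Matrix proteolysis was −0.035 for slow and −0.067 for plate over before culture. For slow over before culture cytotoxic genes were −0.12, inhibitory receptors 0.028 and CD4 and regulatory T cell markers 0.21. For slow over fast NF-kB targets were −0.055 and the T cell receptor response −0.21, which was −0.13 for slow over plate. The cytotoxic list of fast over plate was 0.20. Named genes that reversed in G1 cells for slow over fast were IFNG −0.27, TNFRSF4 −0.017, PTGER4 −0.097, TRAF1 −0.12 and RELB −0.17. For fast over plate they were GZMH 0.58, CTLA4 0.16 and YPEL3 0.16, and for slow over plate TNFRSF4 −0.13, KLRD1 0.057, HLA-DMB 0.18, PSRC1 0.61 and TSC22D3 0.046. Over before culture they were FOS −1.23, TXNIP −0.29, SATB1 0.34, HLA-DPB1 −0.15, HLA-DRB1 −0.81, HLA-DPA1 −0.57, HLA-DRA −0.97 and NEK2 −0.35 in the fast library. In the slow library they were FOS −0.38, JUN −0.29, TXNIP −0.74, SATB1 0.48, ZEB2 −0.70, SRGN −0.052, GNLY −1.50, CTLA4 0.21, TIGIT 0.028, DUSP1 −0.69, HLA-DPB1 −0.051, HLA-DRB1 −0.58, HLA-DRA −0.80, HLA-DPA1 −0.37, KIF11 −0.078 and NEK2 −0.93. In the plate library they were FOS −1.60, ATF3 −0.90, TXNIP −0.24, ID3 −0.66, SATB1 0.54, ZEB2 −0.61, GNLY −1.27, HLA-DRB1 −0.38, HLA-DRA −0.86, NEK2 −0.92, KIF11 −0.068 and DLGAP5 −1.15.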

Other observations

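Of the tests in this part, those of a small group of cells, of the cluster led by p53 targets, of damaged cells low in mitochondrial UMIs and of cells other than T cells were chosen after the result was seen.

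Clusters other than the T cell clusters held a larger share before culture than at day 3. The T cell clusters held 86.0% of cells before culture and 98.7%, 95.4% and 99.4% in the fast, slow and plate libraries. A cluster led by haemoglobin genes held 362 of 6593 cells before culture (5.49%, 95% interval 4.95 to 6.07), and 9, 10 and 1 cells in the fast, slow and plate libraries. A natural killer cell-like cluster held 290 cells before culture (4.40%, 3.92 to 4.92) and 15, 6 and 10 cells at day 3, with a median depth of 4599 UMIs before culture against 31743 in the T cell clusters. The B cell-like cluster held 104 cells before culture and 17, 8 and 13 at day 3. The other 2 clusters, left unnamed, held 167 cells before culture (2.53%) and 21 (0.428%), 130 (3.92%) and 3 (0.069%) in the fast, slow and plate libraries. Their median mitochondrial shares were 0.737%, 0.309%, 0.471% and 0.256% in the same order. In these clusters, numbered 14 and 16, CD3D stood at 450 and 365 CPM, against 517 CPM in other clusters. TRAC stood at 469 and 228 CPM, against 548 CPM. A CD3E UMI was found in 61.4% and 75.9% of their cells, below the limit set for T cell clusters. Their median depths were 5148 and 5918 UMIs, so shallow T cells may have missed that limit. The lists of natural killer, B and plasma, myeloid, erythroid and platelet, and fibroblast and endothelial markers had fewer than 5 measured members in each comparison. Phases called on thinned cells were S for 48.1% of cells before culture and 36.6%, 34.6% and 38.3% at day 3 in the fast, slow and plate libraries, and G1 for 2.40%, 5.10%, 7.08% and 5.40%. Free RNA enters these calls, so they are not read as cycling.

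Summed over 18 members, the p53 and apoptosis list had a median of 6 UMIs per thinned cell in the slow library, 5 in the fast library, 4 in the plate library and 4 before culture. The 10th percentiles were 3, 2, 2 and 1, the 25th 4, 3, 3 and 2, the 75th 10, 7, 6 and 6 and the 90th 13, 9, 8 and 8 UMIs. The glycolysis list, summed over 19 members, had medians of 60, 61 and 67 UMIs in the slow, fast and plate libraries and 90th percentiles of 77, 80 and 113.

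A hypothesis is that T cells in the slow relaxing matrix may carry a stronger p53 response than those in the fast relaxing matrix, where the list's median log2 fold was 0.74. A greater weight of deeper cells in the summed counts is argued against by a median of 0.73 with cells thinned to equal depth. Thinning does not test whether deeper cells themselves differ. Cells high in mitochondrial UMIs or low in genes are argued against by 0.70 with the stricter cell filter. Damaged cells low in mitochondrial UMIs are argued against by 0.72 when those under 1% were left out as well. The cluster led by p53 targets held 659 slow, 119 fast and 15 plate cells, grouped partly by the genes compared, and carried part of the difference. With its cells left out the median was 0.58. Were these cells the only source, free RNA would have to carry 74.0% of the excess to the other cells. T cell genes in 8 B cell-like slow cells had a median of 5.86% of their level in T cells. In B cell-like cells of all libraries, however, CD3D stood at 194 CPM, against 520 CPM in the other clusters. Of these 142 cells 104 came from before culture, and no doublets were removed, so that level need not be free RNA alone. Free RNA was thus not measured closely. The value of 0.58 argues against the cluster led by p53 targets as the whole cause only if free RNA did not carry the rest. Whether a small group of cells carries the difference cannot be told apart from a shift of most cells: the share of thinned cells with at most 5 list UMIs was 39.4% against 59.7%, a ratio of 0.66 (95% interval 0.629 to 0.693), which free RNA also lowers, and 8 B cell-like cells are too few to measure it closely. The matrix and the library coincide, so a difference in preparation stays open.

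A further hypothesis is that T cells on the plate may have met less oxygen than those in the matrices, where the hypoxia list had medians of −0.53 (fast) and −0.60 (slow) over the plate library. A greater weight of deeper cells in the summed counts is argued against by −0.55 in the fast and −0.55 in the slow library with thinned cells. Cells other than T cells are argued against by −0.53 and −0.60 within the T cell clusters. Another mix of cell cycle phases cannot be told apart: weighting phases as in the plate library gave −0.55 and −0.59, but the called shares differed by at most 2.04 and 3.75 points, so the weighting had little to move, and free RNA enters the calls. Culture format, cell density and library coincide with the groups and stay open, and oxygen was not measured in these data.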
